A study of Ovis aries with 8 samples.

How the data were processed

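Total RNA was extracted from liver pieces kept in RNAlater, and libraries of polyadenylated RNA were made and sequenced from both ends on an Illumina HiSeq instrument, one library per lamb, in 4 ADL and 4 RES lambs. Groups, lamb numbers, milk allowance, weight and age at slaughter were taken from the labels. Per the submitters' processing notes, bcl2fastq 1.8.4 and DESeq2 1.12.4 were used; the aligner, the read counter and the genome build are not given in the sources used here. Gene coordinates are those of the deposited table, and a gene listed on chromosome Un there has no position.

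The deposited table holds 27729 genes. Its expression values are the authors' TPM, reads scaled to gene length and library total, one column per lamb. The authors' DESeq2 comparison of the groups gives, per the file headers, a shrunken log2 fold change with its standard error, the maximum likelihood value beside it, a test score, a p-value and an adjusted p-value per gene. TPM divides by a gene length that the same table lists, and each lamb's values add to the same total, so a rise in a few abundant genes lowers the TPM of all others. Because every deposited TPM times gene length was a whole multiple of one step per lamb, whole reads per gene were recovered (100% of values above 0 were whole within 0.001). Means of these reads after median-of-ratios scaling equalled the authors' deposited means in 22465 genes (ratio 1). The recovered totals, 15134039 to 17879918 reads per lamb, are the depth of each library. No count model was refitted to them beyond the voom alternative, and the authors' deposited results are given as theirs. Reads of similar or overlapping genes can be counted for the wrong copy, which was not tested here.

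Genes with a mean TPM of at least 1 over the lambs compared were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trended prior) on log2(TPM + 0.5), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are RES over ADL. Weight, age and library measures were compared by two-sided exact permutation tests of the difference in means over 70 assignments, adjusted over 8 measures. Positions between groups were computed on log2 values, with each lamb left out of its own group's mean. Correlations between lambs are across genes, which are not independent replicates.

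Gene lists written before the data were examined, 36 of pathways and 11 of cell type markers and RNA quality, were tested with camera at a preset correlation of 0.01 where at least 5 tested members (3 for markers) were present, adjusted over the lists of each kind. Camera with an estimated correlation, a rank-based camera and fry were run beside it. Fry asks whether the genes of a list move one way on balance, or change in either direction, and compares the list with no other genes. List names were matched first by the table's symbol, then through the Entrez identifier in a reference of gene names (21951 identifiers) and then by the table's alias, which found 873 of 969 names (831, 28 and 14). The latter steps were settled after a run with table symbols alone had been seen, and that run is given as an alternative. A list's score in a lamb is the mean log2 deviation of its tested members from the mean of the 8 lambs. Genes can belong to more than one list.

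Named genes were chosen by a rule written before the data were examined. With fewer than 10 genes past the threshold it takes the 10 genes in each direction with the smallest p, and otherwise the 12 in each direction with the largest fold change among those that pass, carry a symbol and separate the groups. It adds up to 4 passing members of each list, or the member with the smallest p where none passes, and 14 genes of growth, fasting and lipid metabolism, of which CYP7A1 was not analysed here. The same rule was applied to the fit without ADL 3, a use chosen after the data had been seen. Some genes that the rule names are not reported here; they stay in every test and are left out of counts over named genes.

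The procedure was tested on simulated reads with the depth and spread of these lambs, in which 100 genes changed by 2-fold, 100 by 4-fold and a further list of genes by less. With 8 lambs it found 48% and 91% of them, with 10 false calls among 155. Without ADL 3 it found 46% and 87%, with 10 false among 147. Reads were drawn for each gene on its own, so no simulated lamb stood apart across genes, as ADL 3 did in the data. The shares found are therefore not an estimate of what could be found in these lambs. Alternatives were other pseudocounts (0.1 and 1), other filters on low values, median-of-ratios and quantile scaling, age as a covariate, lamb number as a block, a constant or robust prior, sample quality weights, a permutation test per gene and leaving out each lamb in turn. Alternatives chosen after seeing the data were voom on recovered reads, the acute phase list score as a covariate, list names matched by table symbol alone, and the rescaled, voom and age fits without ADL 3. All columns of values in the deposited table belonged to the 8 lambs.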

Results

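Liver RNA was sequenced from 8 preweaning Assaf lambs fed milk replacer at 2 levels, to ask how restriction of the milk replacer alters gene expression in the liver. The 4 ADL lambs (ADL 1 to ADL 4) drank ad libitum, with an allowance of 192 mL per kg, and the 4 RES lambs (RES 1 to RES 4) were restricted to 120 mL per kg. Each library came from a separate lamb. Between 15134039 and 17879918 reads were assigned to genes per lamb. Values after ± are SDs, with n = 4 in each group.

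The RES lambs were lighter at slaughter, at 7.9 ± 0.548 kg against 11.6 ± 0.890 kg in ADL (SD, n = 4 each), and every RES lamb weighed less than every ADL lamb (exact permutation p = 0.0286, two-sided, the smallest that 70 assignments allow; 0.229 after adjustment over 8 library and animal measures). Age at slaughter was 34.3 ± 1.5 days in RES and 35 ± 1.41 days in ADL (exact permutation p = 0.743, n = 4 each). RES livers had 198 fewer genes with a TPM above 0, 19382 ± 122 against 19580 ± 77.3 (exact permutation p = 0.0571, n = 4 each). Genes at a TPM of at least 1 numbered 13602 in RES and 13694 in ADL (exact permutation p = 0.543, n = 4 each). The 10 most abundant genes took 22.1 ± 2.88% of all TPM in RES and 23.1 ± 5.39% in ADL (exact permutation p = 0.8, n = 4 each), with 31.0% in ADL 3 and 18.7 to 22.0% in the other ADL lambs. Without ADL 3 the difference in this share changed sign, from -1.07 to 1.54 percentage points. Mitochondrially encoded genes took 6.66 ± 1.17% of TPM in RES and 7.42 ± 2.94% in ADL (exact permutation p = 0.743, n = 4 each), with the lowest share, 4.39%, in ADL 3. Leaving out ADL 1, the lamb with the highest share (11.4%), turned that difference from -0.76 to 0.56 percentage points. Haemoglobin genes took 0.00636% in RES and 0.0028% in ADL (exact permutation p = 0.457, n = 4 each).

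Across all tested genes, ADL 1, ADL 2 and ADL 4 lay apart from the RES lambs, and ADL 3 did not lie with them. The first principal component held 38.1% of the variance and placed ADL 1, ADL 2 and ADL 4 between -46.2 and -34.3, the RES lambs between 14.8 and 20.6 and ADL 3 at 46.3. On the second component (22.2%), RES 1, RES 2 and RES 3 lay between 24.1 and 28.9, whereas RES 4 (-22.8) and ADL 3 (-36.5) lay at the other end. On an axis that runs from 0 at the mean of a lamb's own group mates to 1 at the mean of the other group, ADL 3 was at 1.04, RES 4 at 0.61 and the other 6 lambs between -0.04 and 0.21. The mean correlation of ADL 3, across genes, was 0.929 with the other ADL lambs and 0.956 with the RES lambs.

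**Figure D1:**
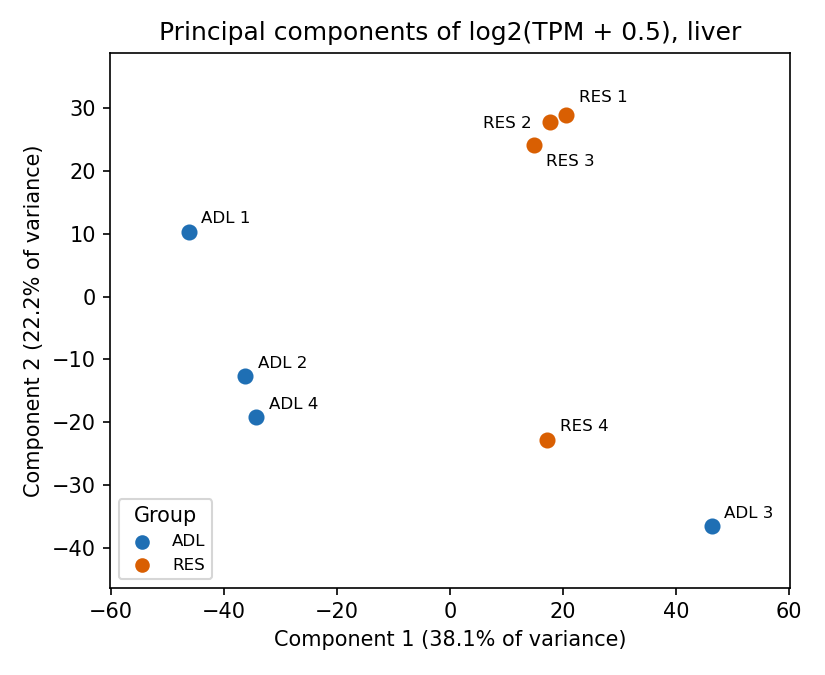
Principal components of log2(TPM + 0.5), with component 1 on the horizontal and component 2 on the vertical axis and each point a lamb (blue ADL, orange RES). ADL 1, ADL 2 and ADL 4 lie at -46.2 to -34.3 on component 1, the RES lambs at 14.8 to 20.6 and ADL 3 at 46.3.

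In the comparison of all 8 lambs, LOC101103439, annotated as cytochrome P450 26A1 (CYP26A1, an enzyme that clears retinoic acid), rose in RES from 4.72 ± 0.243 to 38.8 ± 16.8 TPM (SD, n = 4 each). Its log2 fold change was 2.82 (SE 0.27, limma adjusted p = 0.0188), and it was the 1 gene of 13812 tested to pass. The gene lies on chromosome 22 at 14076891 to 14080577 and has 8 exons in the coordinates of the authors' deposited table, whose genome build is not given in the sources used here. Its range over the lambs was 4.47 to 5.04 TPM in ADL, ADL 3 included, and 21.9 to 61.7 TPM in RES. The call was lost when ADL 1, ADL 2, ADL 4, RES 1 or RES 3 was left out in turn, when TPM were rescaled by median of ratios, without the filter on low values, with lamb number as a block, with voom on recovered reads and with an acute phase covariate. Over these and the other alternatives its adjusted p ran from 0.00194 to 0.164 and its log2 fold change, with a lamb left out, from 2.56 to 3.05.

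The 9 genes that followed CYP26A1 among those higher in RES did not pass (adjusted p = 0.108 to 0.166). They included ADH1C, a class I alcohol dehydrogenase on chromosome 6 at 25267563 to 25286866, with 729 ± 79.5 TPM in ADL and 1648 ± 118 in RES (log2 fold change 1.18, SE 0.16, adjusted p = 0.108). An alcohol dehydrogenase 6-like gene (LOC101123194) had 276 ± 59.2 and 1123 ± 588 TPM. Glycine N-acyltransferase (GLYAT, LOC101108685), which conjugates acyl groups to glycine in mitochondria, had 208 ± 87 and 747 ± 91.6 TPM (log2 fold change 1.92, SE 0.27). Genes annotated as cytochrome P450 2D14 (LOC101105651) and cytochrome P450 2D14-like (LOC101112384) had 163 and 252 TPM in ADL and 554 and 858 TPM in RES, and whether they share reads was not tested. ATF5, a transcription factor of the stress response in mitochondria, had 101 ± 33.2 and 526 ± 207 TPM (log2 fold change 2.30, SE 0.37, adjusted p = 0.166). SH3RF2 and the uncharacterized LOC105605792 had log2 fold changes of 1.2 and 1.79. The uncharacterized LOC105616212 was listed at 0 in all ADL lambs and at 0.846 to 4.47 TPM in RES.

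Among genes lower in RES, the 10 with the smallest p did not pass either (adjusted p = 0.182 to 0.272). ACMSD, which directs tryptophan breakdown away from NAD synthesis, had 90.6 ± 53.1 TPM in ADL and 11.7 ± 4.93 in RES (log2 fold change -2.70, SE 0.51), with 23.7 TPM in ADL 3. XDH, the xanthine dehydrogenase of purine breakdown, had 86.0 ± 53.3 and 13.3 ± 2.28 TPM (log2 fold change -2.39, SE 0.47), with 24.9 TPM in ADL 3. The small heat shock protein CRYAB, the caveolar protein CAV1 and the lipocalin APOD had log2 fold changes of -0.98, -1.14 and -1.82, and in these ADL 3 lay with the other ADL lambs, as it did in COLEC12 (-0.81), HTATIP2 (-1.04), ASPA (-1.06) and LOC101112919 (-1.31). The uncharacterized LOC106991607 had a log2 fold change of -2.73.

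An unadjusted p under 0.05 was reached by 1340 genes, against 691 expected by chance. In 619 genes (4.48%, against 2.86% or 395 genes by chance) the 4 RES values lay all above (387) or all below (232) the 4 ADL values. An exact permutation test per gene put 622 genes at its smallest p, 0.0286, against 395 expected. That p is reached where the groups separate, so this count nearly repeats the 619 and is not a second line of support. Genes are not independent, and whether these excesses exceed those of other splits was not tested. The authors' deposited table lists an adjusted p for 16794 of 27729 genes, with 386 below 0.05, of which 210 were higher and 176 lower in RES. Of those 386 in the authors' deposited table, 359 were tested with limma, all 359 had the same sign there and 356 had an unadjusted limma p under 0.05. CYP26A1 had an adjusted p of 9.04e-17 and a log2 fold change of 2.51 in the authors' deposited table, and ADH1C, GLYAT, ATF5, ACMSD and XDH were below 0.05 there as well.

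Genes of growth, fasting and lipid metabolism that were named before the data were examined did not pass in the 8 lambs. The growth factor gene IGF1 had 24.8 ± 9.05 TPM in ADL and 38.1 ± 14.9 in RES (log2 fold change 0.61, SE 0.34, adjusted p = 0.626), and its regulator GHR had a log2 fold change of 0.47. IGFBP1, FGF21 and CYP2E1 had log2 fold changes of 0.11, 0.64 and 0.44 (adjusted p = 0.68 to 0.958). The sterol and fatty acid synthesis genes SREBF1, FASN and SCD had log2 fold changes of 0.91, 0.62 and 1.06 (adjusted p = 0.309 to 0.549). Their levels were low, at 3.65, 1.3 and 2.36 TPM in ADL and 7.81, 2.25 and 6.68 TPM in RES. CPT1A, which sets the rate of fatty acid entry into mitochondria, had a log2 fold change of -0.51 (adjusted p = 0.756), and PDK4, which restrains pyruvate oxidation, -1.21 (adjusted p = 0.669). PCK1 of gluconeogenesis had a log2 fold change of 0.57 (adjusted p = 0.535). CYP7A1 was not analysed here.

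With ADL 3 left out, as each lamb was in turn, 1382 of 13815 genes passed. Which lamb to single out was clear only after its effect had been seen. APOA4, an apolipoprotein of triglyceride-rich particles, fell by 7.26 on the log2 scale (SE 0.82, adjusted p = 0.00377), with 328 to 3556 TPM in ADL 1, ADL 2 and ADL 4, 3.14 to 16.6 TPM in RES and 10.8 TPM in ADL 3. SDS, which converts serine to pyruvate, fell by 5.29 (SE 1.01, adjusted p = 0.022), with 2548 to 6042 TPM in these ADL lambs, 31.1 to 68.9 TPM in RES 1, RES 2 and RES 3, 862 TPM in RES 4 and 63.0 TPM in ADL 3. GNMT, which consumes methyl groups of S-adenosylmethionine, fell by 4.69 (SE 0.28, adjusted p = 0.000649). The fatty acid elongase ELOVL7 and the lysophospholipid transporter MFSD2A each fell by 4.42. The aminotransferase GOT1 fell by 3.86, the lipid droplet protein PLIN2 by 3.69, and MTMR7 (-3.42), glycerol kinase (GK, -3.31), ACMSD (-3.25) and cystathionine gamma-lyase (CTH, -3.23) also fell. NMRK2, a kinase of NAD synthesis, was listed at 0 in all RES lambs and in ADL 3 and at 1.36 to 9.23 TPM in the other ADL lambs.

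Genes that rose without ADL 3 included the cotransporter SLC12A1 (log2 fold change 3.03, SE 0.32, adjusted p = 0.00261) and mitochondrial ALDH1L2 of folate metabolism (2.97, SE 0.22, adjusted p = 0.000822). OSGIN1 and TSKU each rose by 2.95, the transporter ABCC11 by 2.75 and the desaturase FADS1 by 2.73, from 13.5 ± 4.58 TPM in 3 ADL lambs to 103 ± 65.2 in 4 RES lambs (SD). CUX2, TNFRSF9, tryptophan hydroxylase 1 (TPH1), the acyltransferase GLYATL3, ATF5 and the proline synthesis gene PYCR1 rose by 2.48 to 2.67 (adjusted p = 0.011 to 0.0288). In several of these ADL 3 lay near RES, with 16.4 TPM of ALDH1L2 against 1.14 to 2.44 in the other ADL lambs and 13.9 to 20.4 in RES. In others ADL 3 lay near its group, with 21.9 TPM of FADS1 against 8.31 to 17 in the other ADL lambs and 39.6 to 193 in RES. CYP26A1 was the 1 gene called both with and without ADL 3. Of the named genes of fasting and lipid metabolism, PDK4 (-2.04), PCK1 (0.82) and FASN (0.71) passed without ADL 3 (adjusted p = 0.0325 to 0.0389), and PDK4 did not after rescaling (0.0533). FASN lay near the filter on low values, at 1.18 TPM in ADL 1, ADL 2 and ADL 4 and 2.25 TPM in RES.

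**Figure D2:**
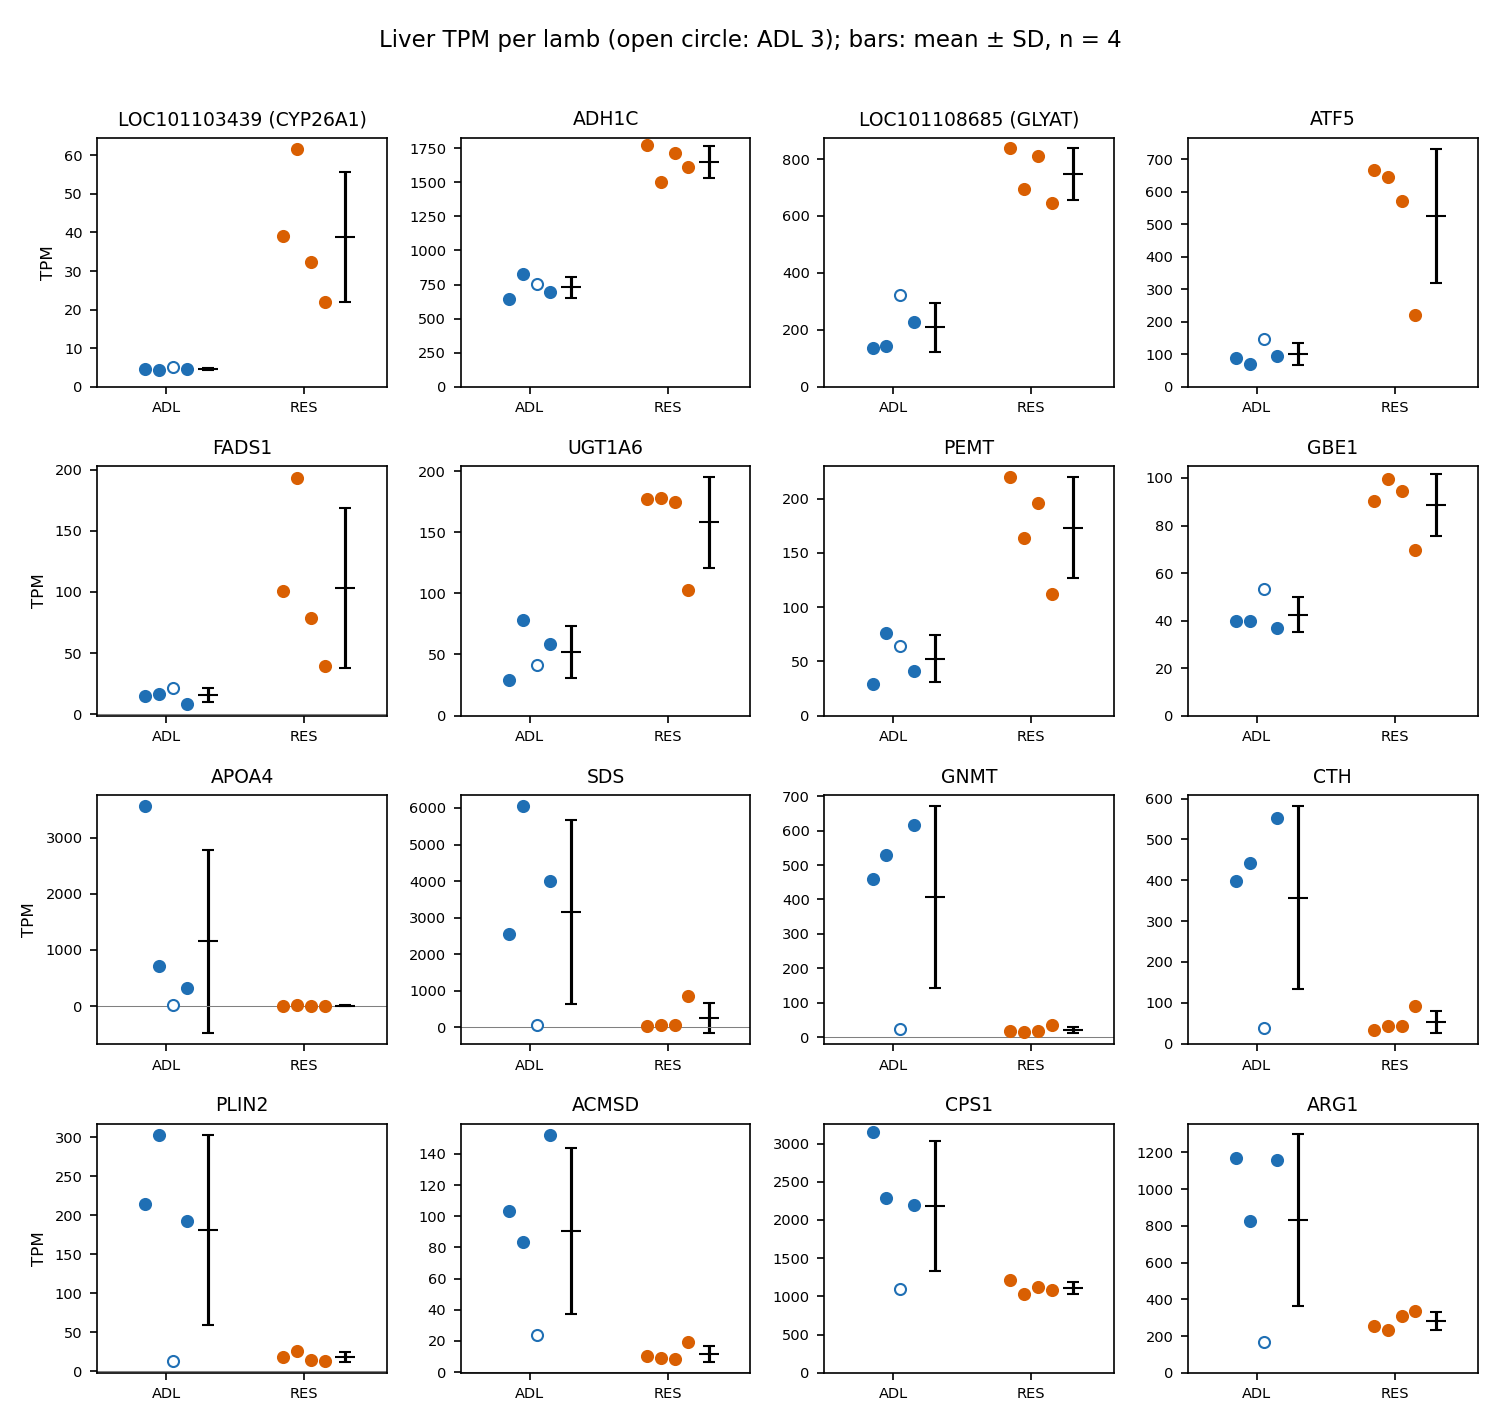
TPM of 16 genes per lamb on the vertical axis, by group (points are lambs, the open circle is ADL 3, bars are mean ± SD, n = 4 per group). In the upper 8 panels ADL 3 lies nearer the mean of the other ADL lambs than that of RES, as in CYP26A1 at 5.04 TPM. In the lower 8 panels it lies with RES, as in APOA4 at 10.8 TPM. The 16 genes were picked for display and do not stand for all called genes. Of the genes called without ADL 3, it lay nearer the other ADL lambs on log2 values in 99 of 334 higher and 31 of 1048 lower ones.

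Of the 1382 genes called without ADL 3, 334 were higher and 1048 lower in RES, while the median log2 fold change of all genes was -0.13. After median-of-ratios rescaling without ADL 3, 1171 genes passed, 619 higher and 552 lower, with the median of all genes moved to 0.01. Sample quality weights, which gave ADL 3 the lowest weight (0.16), called 1969 genes, of which 1158 were among the 1382. Leaving out RES 4 gave 49 genes, 38 higher and 11 lower, and leaving out each of the other lambs gave 0 or 1. Of the 386 genes called in the authors' deposited table, 233 were among the 1382.

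The fixed gene lists were tested next, 36 for pathways of liver metabolism, growth, stress and immunity. With camera at its preset correlation, 18 of the 36 lists passed, 14 higher and 4 lower in RES. None passed with an estimated correlation (smallest adjusted p = 0.387, and 3 at an unadjusted p under 0.05). In the rank-based test 17 passed, with 0 in fry (smallest adjusted p = 0.212) and 7 in fry for change in either direction. List scores per lamb were also compared by exact permutation tests, unadjusted, n = 4 each. The exact permutation p was 0.0286 for cholesterol synthesis, phase I enzymes and extracellular matrix. In the other lists that passed camera, the exact permutation p ran from 0.0571 (cell cycle among them) to 0.371 (pericentral hepatocyte genes). Lists said below to rise or fall were thus called across genes, and most did not reach 0.05 across lambs. Limma called no member of any list over all genes in the 8 lambs, where 1340 of all genes had an unadjusted p under 0.05. Counts adjusted over the list alone and counts over all genes without ADL 3 are therefore given beside each list.

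Mean scores of the lists of gluconeogenesis, the urea cycle and periportal hepatocytes were higher in ADL 1, ADL 2 and ADL 4 than in each RES lamb and in ADL 3, though single members differed. The gluconeogenesis list fell in the 8 lambs (12 of 13 tested members lower, median log2 fold change -0.50, adjusted p = 0.00842; adjusted p = 0.523 with an estimated correlation). Its mean score per lamb, the log2 deviation from the mean of all 8, was 0.71 to 1.08 in those 3 ADL lambs, -0.65 to -0.16 in RES and -1.04 in ADL 3. No member passed when adjusted over the list alone, and without ADL 3 the median was -0.96, with 6 members lower and PCK1 higher over all genes. These included the glucose-6-phosphate transporter SLC37A4 (-1.51, SE 0.13, adjusted p = 0.00138) and pyruvate carboxylase (PC, -1.43). The call was lost without ADL 2 (adjusted p = 0.0544). The urea cycle list did not pass (6 of 8 lower, median -0.79, adjusted p = 0.119; none adjusted over the list alone), and passed without ADL 3 (median -1.26, adjusted p = 0.0231; adjusted p = 0.38 with an estimated correlation). Without that lamb CPS1, the entry enzyme of the cycle, ARG1, ASS1 and ASL fell by 1.18, 1.88, 1.64 and 1.47 and 5 of 8 members passed over all genes. CPS1 had 2202 to 3152 TPM in ADL 1, ADL 2 and ADL 4, 1033 to 1212 in RES and 1093 in ADL 3. The periportal list fell (11 of 14 lower, 1 lower adjusted over the list alone, median -0.64, adjusted p = 0.0141; adjusted p = 0.511 with an estimated correlation). Its scores were 0.74 to 0.89 in those 3 ADL lambs, -0.74 in ADL 3 and -0.55 to -0.22 in RES, and without ADL 3 the median was -1.07 with 6 members lower and 1 higher, among them GLS2 (-1.65). PIGR, the receptor that carries immunoglobulin into bile, had 50.3 ± 33.5 TPM in ADL and 10.7 ± 2.07 in RES and was highest in ADL 3.

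Amino acid catabolism genes moved in both directions, with 5 of 42 tested members higher and 8 lower when adjusted over the list alone. The list did not pass (median 0.02, mean -0.42, adjusted p = 0.669), and its median reversed without ADL 3 (-0.14) and under quantile normalization. Without ADL 3, 13 members fell and 7 rose over all genes, with GNMT, ACMSD, CTH and SDSL (-2.80, SE 0.21, adjusted p = 0.000865) among the former. One carbon and methionine metabolism did not pass (10 of 19 higher, 1 higher and 1 lower adjusted over the list alone, median 0.17, mean -0.16, adjusted p = 0.579), and its median was -0.02 without ADL 3, where 4 members fell and 1 rose. PEMT, which uses methyl groups to make phosphatidylcholine, had 52.5 ± 21.7 TPM in ADL and 173 ± 46.6 in RES (log2 fold change 1.77, SE 0.32, adjusted p = 0.182), and without ADL 3 it rose by 1.90. Cystathionine beta-synthase (CBS) fell by 1.28 without ADL 3.

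Target genes of the fatty acid sensor PPARA fell as a list in the 8 lambs (12 of 15 lower, median -0.47, adjusted p = 0.0438; adjusted p = 0.639 with an estimated correlation), with scores of 0.47 to 1.03 in ADL 1, ADL 2 and ADL 4, -0.81 to 0.09 in RES and -1.02 in ADL 3. ANGPTL4, an inhibitor of lipoprotein lipase, was the 1 member lower when adjusted over the list alone, with 206 ± 99.2 TPM in ADL and 53.3 ± 31.7 in RES (log2 fold change -1.96, SE 0.44, adjusted p = 0.272 over all genes). Without ADL 3 the median was -0.94 and 6 members fell over all genes, PLIN2, ANGPTL4 (-2.27) and the transcription factor CREB3L3 (-1.85) among them, of which 4 passed after rescaling. The call was lost when ADL 1, ADL 2, RES 3 or RES 4 was left out (adjusted p up to 0.277), with sample weights and with other filters on low values. Fatty acid oxidation did not pass (14 of 23 lower, none adjusted over the list alone, median -0.16, adjusted p = 0.579). Without ADL 3 its median was -0.32 and 4 members fell, the carnitine transporter SLC22A5 (-2.34), the acyl-CoA synthetase ACSL1 (-1.93) and ACAA2 (-0.91) among them; after rescaling 2 members passed as lower, ACAA2 not among them, and 1 as higher. ECHS1 of the same list had a log2 fold change of 0.55 in the 8 lambs. Ketone body synthesis did not pass (4 of 5 lower, none adjusted over the list alone, median -0.35, adjusted p = 0.417).

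Triglyceride and lipoprotein assembly did not pass (10 of 19 higher, 2 lower adjusted over the list alone, adjusted p = 0.302). Its median was 0.02 and its mean -0.58, the median turned to -0.27 without ADL 3, and there APOA4, PLIN2 and LPL (-0.67) fell. The hepatokine and energy sensor list did not pass (14 of 21 higher, 1 higher and 1 lower adjusted over the list alone, median 0.26, adjusted p = 0.115). GDF15, a circulating stress signal, rose by 1.06 and the activin subunit INHBC by 1.92 without ADL 3, where INHBC was at 3.39 to 12.2 TPM in the other ADL lambs, 18.6 to 34.9 in RES and 120 in ADL 3. PRKAG2, a subunit of the energy sensor AMPK, fell by 0.87 without ADL 3 and did not pass after rescaling (adjusted p = 0.0694). Passing without that lamb, the hepatokine members were 2 higher and 2 lower.

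Fatty acid synthesis and desaturation rose in RES (11 of 16 higher, 6 higher adjusted over the list alone, median 0.78, adjusted p = 0.000138; adjusted p = 0.424 with an estimated correlation). TKFC, which phosphorylates dihydroxyacetone and glyceraldehyde, had 10.4 ± 0.728 TPM in ADL and 31.5 ± 10.7 in RES (log2 fold change 1.48, SE 0.25, adjusted p = 0.166), and ADL 3 lay within its group at 11.4 TPM. Without ADL 3, TKFC, FADS1 and FASN were among 5 members that rose, and the elongases ELOVL6 (-1.88) and ELOVL5 (-1.19) were among 3 that fell. Cholesterol synthesis rose (17 of 22 higher, 7 higher and 2 lower adjusted over the list alone, median 0.52, adjusted p = 1.71e-05; adjusted p = 0.424 with an estimated correlation). FDPS, NSDHL and LSS rose by 0.71, 1.16 and 1.2 without ADL 3, whereas the kinases PMVK and MVK fell by 1.67 and 1.41, and 4 members rose over all genes there and 2 fell. Bile acid synthesis and transport rose, with all 11 tested members higher and none past adjusted over the list alone (median 0.31, adjusted p = 0.00397; adjusted p = 0.424 with an estimated correlation). The bile acid uptake transporter SLC10A1 had 51.9 ± 16.7 TPM in ADL and 129 ± 60.1 in RES (log2 fold change 1.17, adjusted p = 0.453). Without ADL 3 the list's median was 0.53 and BAAT (LOC101106409) and SLC51B rose by 1.23 and 1.57, with ADL 3 at 93.6 and 13.8 TPM, above each RES lamb.

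Glycolysis and glycogen genes did not pass as a list (11 of 19 higher, 3 higher adjusted over the list alone, median 0.06, adjusted p = 0.146). The glycogen branching enzyme GBE1 had 42.5 ± 7.4 TPM in ADL and 88.5 ± 13.1 in RES (log2 fold change 1.05, SE 0.18, adjusted p = 0.166). Without ADL 3, GBE1 (1.17) and liver pyruvate kinase PKLR (1.56) were among 3 that rose, and the glycogen synthase GYS2 (-2.01) and UGP2 (-1.15) were among 3 that fell. Insulin and FOXO1 responsive genes did not pass (10 of 18 higher, none adjusted over the list alone, median 0.08, adjusted p = 0.179), and their median was -0.13 without ADL 3, where PCK1 rose and PDK4 and TRIB3 (-0.69) fell, neither of the latter past 0.05 after rescaling. SREBF1 had the smallest p of that list in the 8 lambs.

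Phase I enzymes of drug and steroid metabolism rose (13 of 16 higher, 5 higher adjusted over the list alone, median 0.45, adjusted p = 3.11e-05; adjusted p = 0.387 with an estimated correlation). The aldehyde dehydrogenase ALDH3A2 had 141 ± 32.8 TPM in ADL and 240 ± 14.7 in RES (log2 fold change 0.79, SE 0.19, adjusted p = 0.28). Without ADL 3, ALDH3A2 (0.92), FMO5 (2.41) and AOX1 (1.14) rose over all genes and the median was 0.29. Phase II conjugation enzymes rose (12 of 21 higher, 7 higher and 3 lower adjusted over the list alone, median 0.15, adjusted p = 0.00413; adjusted p = 0.424 with an estimated correlation), which was lost in the rank-based test. UGT1A6, a glucuronosyltransferase, had 51.8 ± 21.2 TPM in ADL and 158 ± 37.3 in RES (log2 fold change 1.66, SE 0.31, adjusted p = 0.182). Without ADL 3, 5 members rose, GLYAT, UGT1A6 and UGT1A9 (1.53) among them, and GSTA4 (LOC101107232, -2.39) fell. UGT1A6 and UGT1A9 overlap on chromosome 1 from position 7005744, so their reads are not separate measurements with certainty. Oxidative stress defence did not pass (12 of 23 higher, 1 higher adjusted over the list alone, median 0.08, adjusted p = 0.0556) and did in several settings, among them median-of-ratios rescaling and leaving out ADL 4 or RES 3. The superoxide dismutase SOD1 had 388 ± 67.5 TPM in ADL and 861 ± 257 in RES (log2 fold change 1.11, SE 0.25, adjusted p = 0.272) and rose by 1.21 without ADL 3, where the median was -0.02.

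Target genes of the stress factor ATF4 rose as a list with 8 lambs (10 of 16 higher, 2 higher adjusted over the list alone, median 0.21, adjusted p = 0.0464; adjusted p = 0.511 with an estimated correlation). This was lost without ADL 1, ADL 3, RES 1 or RES 2 and in most other settings, and without ADL 3 the median was 0.00 (adjusted p = 0.17). ATF5 and the serine synthesis gene PSAT1 (2.28) rose there, and DDIT4 (-0.90) and TRIB3 fell. Pericentral hepatocyte genes rose (8 of 11 higher, none adjusted over the list alone, median 0.40, adjusted p = 0.0289; adjusted p = 0.424 with an estimated correlation), a call lost without ADL 1, ADL 4 or RES 2 and on rescaling. RGN, a calcium-binding lactonase, had 305 ± 223 TPM in ADL and 914 ± 382 in RES and rose by 2.26 without ADL 3, where ornithine aminotransferase (OAT) fell by 1.91. Circadian clock genes rose (13 of 19 higher, 1 higher adjusted over the list alone, median 0.22, adjusted p = 0.0243; adjusted p = 0.424 with an estimated correlation), a call lost without RES 1 (0.0557). The clock output gene HLF had 9.41 ± 2.74 TPM in ADL and 19.7 ± 3.62 in RES (adjusted p = 0.272), and HLF and DBP rose by 1.04 and 1.29 without ADL 3. Thyroid and glucocorticoid responsive genes did not pass (7 of 12 higher, none adjusted over the list alone, median 0.31, adjusted p = 0.179), and their median was 0.10 without ADL 3, where tyrosine aminotransferase (TAT) fell by 0.96. The thyroxine carrier SERPINA7 had 107 ± 25.4 TPM in ADL and 169 ± 34.1 in RES (adjusted p = 0.377).

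Cell cycle genes rose, with 31 of 32 tested members higher and none past adjusted over the list alone (median 0.44, adjusted p = 7.71e-09; adjusted p = 0.454 with an estimated correlation). The list score was 0.91 in RES 3 and 0.41 in RES 1, -0.22 in RES 2, -0.07 in RES 4 and -0.45 to -0.13 in ADL, and the median was 0.25 without RES 3. The replication helicase genes MCM3, MCM5 and MCM2 rose by 0.99, 1.34 and 1.23 without ADL 3. Cytosolic ribosomal protein genes rose by a small amount (66 of 77 higher, none adjusted over the list alone, median 0.22, adjusted p = 3.05e-07; adjusted p = 0.511 with an estimated correlation). RPLP0 had 846 ± 63.8 TPM in ADL and 1099 ± 66.8 in RES (log2 fold change 0.38), no member passed without ADL 3 on deposited TPM and 12 did after rescaling. The growth hormone and IGF list rose (11 of 15 higher, none adjusted over the list alone, median 0.22, adjusted p = 0.0438; adjusted p = 0.424 with an estimated correlation), a call lost without ADL 1, RES 3 or RES 4, on rescaling and with sample weights, and its median was 0.05 without ADL 3. IGFALS, which stabilises circulating IGF, had 9.29 ± 7.09 TPM in ADL and 18.3 ± 2.73 in RES (adjusted p = 0.478).

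Lists of energy production and organelle function did not pass in the 8 lambs. Nuclear encoded oxidative phosphorylation genes had 27 of 51 members lower (median -0.02, adjusted p = 0.841) and reversed to 0.03 on median-of-ratios rescaling. COX5A (-0.69) and NDUFS3 (-0.65) fell without ADL 3, of which NDUFS3 passed after rescaling. The TCA cycle list had 12 of 21 lower (median -0.04, adjusted p = 0.52; 1 higher adjusted over the list alone), and its median was 0.00 on rescaling and -0.17 without ADL 3. The mitochondrial isocitrate dehydrogenase IDH2 had 29.8 ± 2.25 TPM in ADL and 52.2 ± 5.17 in RES (log2 fold change 0.80, SE 0.14, adjusted p = 0.182), and ADL 3 lay within its group at 29.3 TPM. Without ADL 3, IDH2 rose by 0.79 and OGDH (-2.21, SE 0.13, adjusted p = 0.000649), PDHA1 (-0.85) and DLAT (-0.76) were among 7 that fell. The endoplasmic reticulum stress list had 13 of 19 lower (median -0.13, adjusted p = 0.119), with SEL1L at 39.7 ± 5.27 TPM in ADL and 26 ± 1.9 in RES, and the chaperone SDF2L1 at 142 TPM in ADL 3 against 16.1 to 28.8 in the other ADL lambs and 41.9 to 70.3 in RES. Autophagy and lysosome genes had 12 of 19 higher (median 0.06, adjusted p = 0.264) and a median of -0.04 without ADL 3, where the kinase ULK1 rose by 0.64 and GABARAPL1 fell by 0.65, the latter with an adjusted p of 0.0503 after rescaling. Iron and metal handling had 9 of 16 lower (median -0.06, adjusted p = 0.916), and the zinc importer SLC39A4 fell by 0.81 without ADL 3. None passed adjusted over the list alone for oxidative phosphorylation, endoplasmic reticulum stress, autophagy or iron.

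**Figure D3:**
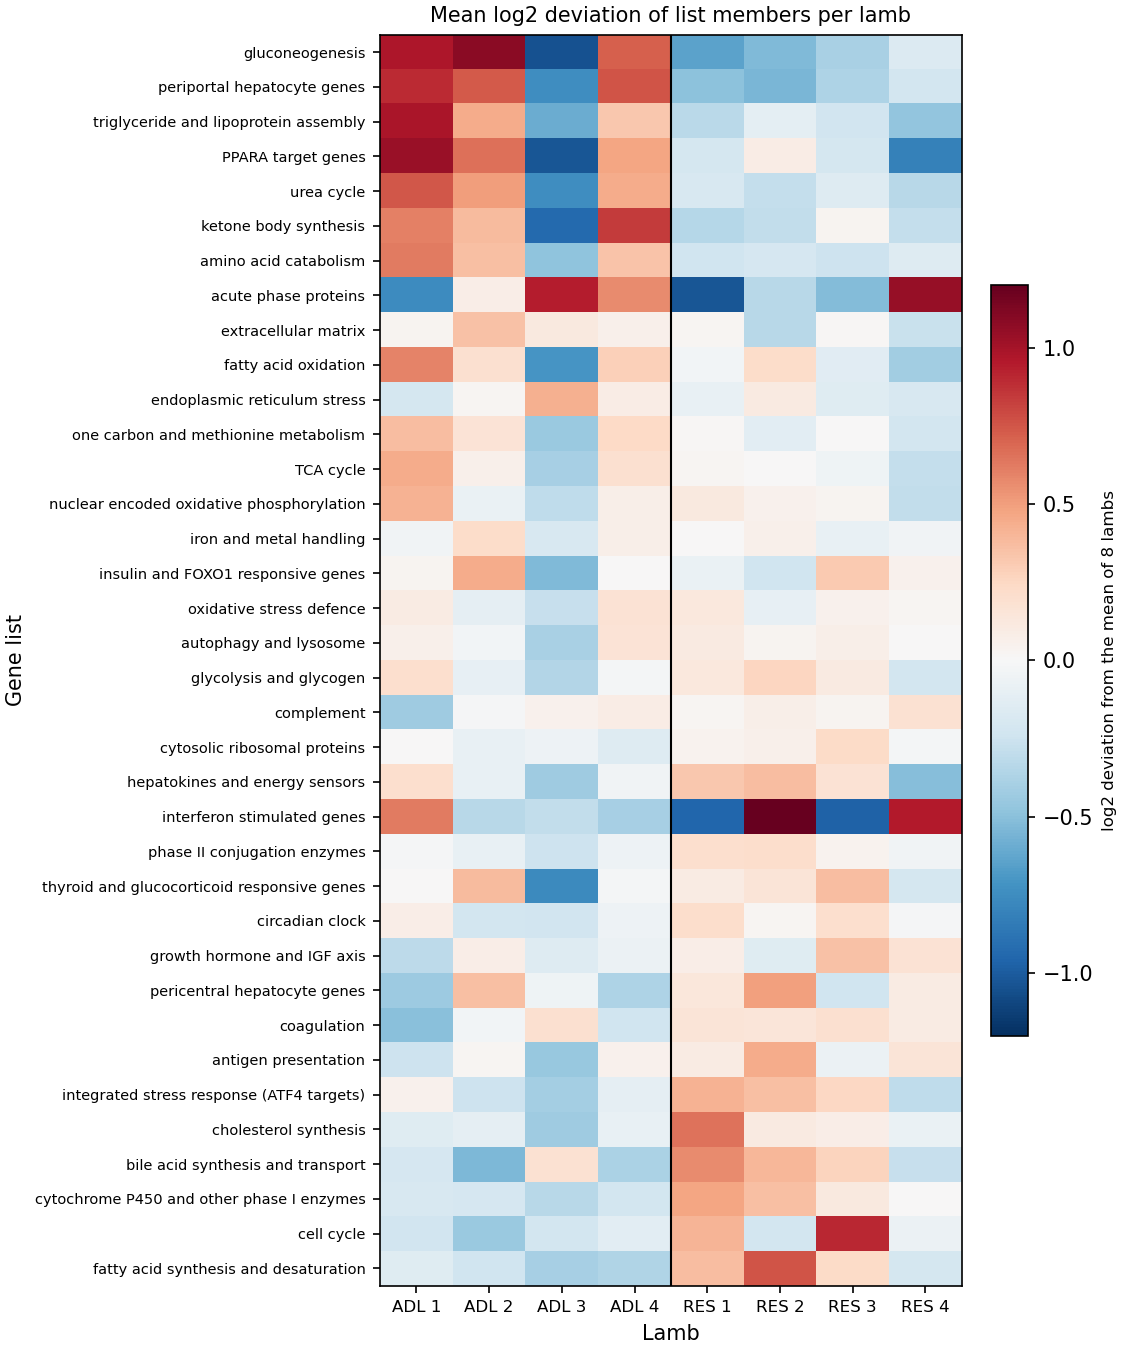
Heat map of the 36 pathway lists (vertical axis) in the 8 lambs (horizontal axis), coloured by the mean log2 deviation of list members from the mean of the 8 lambs and ordered by RES minus ADL. Gluconeogenesis runs from 1.08 in ADL 2 to -1.04 in ADL 3, and interferon stimulated genes from -0.97 in RES 3 to 1.38 in RES 2, beyond the colour scale.

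Among genes of plasma proteins and immunity, coagulation genes rose (19 of 24 higher, none adjusted over the list alone, median 0.37, adjusted p = 4.48e-05; adjusted p = 0.424 with an estimated correlation). F13B, the carrier subunit of factor XIII, had 194 ± 28 TPM in ADL and 325 ± 70.5 in RES (log2 fold change 0.72, SE 0.21, adjusted p = 0.306). Without ADL 3, 5 members rose over all genes, among them the plasmin inhibitor SERPINF2 (1.09), alpha-2-macroglobulin (LOC101122940, 1.44), F11 (0.93) and KLKB1 (0.65), and in F11 ADL 3 stood at 54.7 TPM, above all other lambs. Complement rose (23 of 26 higher, none adjusted over the list alone, median 0.21, adjusted p = 0.00397; adjusted p = 0.514 with an estimated correlation), a call lost without ADL 1 (0.472) or RES 4 and under quantile normalization. C7 of the membrane attack complex went the other way, with 51.2 ± 7.95 TPM in ADL and 29.5 ± 6.9 in RES (adjusted p = 0.28). Antigen presentation genes rose (13 of 14 higher, 1 higher adjusted over the list alone, median 0.33, adjusted p = 9.84e-05; adjusted p = 0.454 with an estimated correlation), a call lost with sample weights. The immunoproteasome gene PSMB9 had 7.21 ± 0.849 TPM in ADL and 12.1 ± 1.38 in RES (log2 fold change 0.71, SE 0.15, adjusted p = 0.272), and it rose by 0.64 without ADL 3.

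Acute phase proteins and interferon stimulated genes varied within both groups and did not pass. The acute phase list had 13 of 17 lower (none adjusted over the list alone, median -0.27, adjusted p = 0.392), with scores of 1.05 in RES 4, 0.94 in ADL 3 and 0.56 in ADL 4 and of -1.02 in RES 1, and it passed without ADL 1 or RES 4, with a median of -0.71 in each case, while without ADL 3 the median was 0.07. C-reactive protein (CRP) had 4996 ± 767 TPM in ADL and 2696 ± 1946 in RES, where RES 4 was at 5607 TPM and the other 3 RES lambs at 1535 to 1888. The interleukin 1 antagonist IL1RN fell by 1.90 without ADL 3 and did not pass after rescaling (adjusted p = 0.0871). Interferon stimulated genes had 20 of 27 higher (none adjusted over the list alone, median 0.19, adjusted p = 0.122), with scores of 1.38 in RES 2, 0.95 in RES 4, 0.62 in ADL 1 and -0.29 or lower in the other 5 lambs. The list passed without ADL 1, RES 1 or RES 3 and in the rank-based test, and its median turned to -0.13 without RES 2 and -0.06 without RES 4. IFIT5 had the smallest p of that list, with a log2 fold change of 0.35. Extracellular matrix genes fell (19 of 23 lower, none adjusted over the list alone, median -0.22, adjusted p = 0.00397; adjusted p = 0.514 with an estimated correlation), and this was lost with sample weights and without ADL 3 (adjusted p = 0.313), where the metalloproteinase inhibitor TIMP2 fell by 1.82 (SE 0.14, adjusted p = 0.000822).

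Markers of the cell types of liver and signs of RNA quality were tested as 11 further lists, of which 2 passed with camera, none with an estimated correlation (smallest adjusted p = 0.833), 1 in the rank-based test and none in fry (smallest adjusted p = 0.439; 2 for change in either direction). T and natural killer cell markers rose (10 of 13 higher, median 0.42, adjusted p = 0.00747; adjusted p = 0.833 with an estimated correlation), a call lost without ADL 1 (0.167) and with sample weights, and NKG7 had 5.91 ± 0.312 TPM in ADL and 9.12 ± 1.99 in RES. Cholangiocyte markers fell (10 of 12 lower, 4 lower adjusted over the list alone, median -0.28, adjusted p = 0.0134; adjusted p = 0.833 with an estimated correlation), a call lost without ADL 3 (0.584), in the rank-based test and with sample weights. Keratin 19 (LOC101117946) had 8.19 ± 3.45 TPM in ADL and 2.63 ± 0.979 in RES. Across lambs, the exact permutation p of the score was 0.114 for T and natural killer cell and 0.0857 for cholangiocyte markers (n = 4 each). Hepatocyte markers had 10 of 15 higher (median 0.07, adjusted p = 0.323), with CPS1 and TAT, which fell without ADL 3, among the others. Kupffer cell and macrophage markers had 8 of 14 higher (median 0.04, adjusted p = 0.323), with C1QA at 236 ± 32.5 TPM in ADL and 310 ± 11.1 in RES.

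Sinusoidal endothelial markers had 9 of 13 lower (median -0.03, adjusted p = 0.663) and stellate cell and fibroblast markers 9 of 15 lower (median -0.04, adjusted p = 0.729), and both medians turned above 0 on median-of-ratios rescaling. LYVE1 and PDGFRA fell by 0.99 and 0.56 and ACTA2 rose by 1.04 without ADL 3, of which ACTA2 passed after rescaling, and COL3A1 had a log2 fold change of -0.37 in the 8 lambs. Erythroid markers had 3 of 3 higher (median 0.12, adjusted p = 0.729; GYPC 0.12). B and plasma cell markers had 2 of 4 higher (median 0.04, adjusted p = 0.828; CD79A 0.52) and reversed without ADL 3 (-0.16). Neutrophil and monocyte markers had 9 of 11 higher (median 0.32, adjusted p = 0.323). Lactotransferrin (LTF) was lower in RES, with 2.07 ± 1.6 TPM in ADL and 0.299 ± 0.183 in RES. Without ADL 3, LTF fell under the filter on low values and was not tested. The 10 members left then passed as a list (median 0.55, adjusted p = 0.0232, and adjusted p = 0.83 with an estimated correlation). What the loss of LTF added to this pass was not tested. Mitochondrially encoded genes had 10 of 13 lower (median -0.06, adjusted p = 0.729), with ND4L at 9868 TPM in ADL 1 and 3486 in ADL 3. Immediate early and heat shock genes had 15 of 24 lower (median -0.15, adjusted p = 0.796), with scores of -1.04 in ADL 3 and 0.28 to 0.62 in the other ADL lambs. Without ADL 3 their median was -0.48 and HSPA8, HSPA1A, HSPH1 and DNAJA1 (-0.99, -1.46, -1.33 and -0.93) were among 5 that fell, whereas KLF4 had a log2 fold change of -0.47 in the 8 lambs. None of the markers passed adjusted over the list alone outside the cholangiocyte list.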

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

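In this part, the tests of swapped labels, of a RES liver under the ADL 3 label, of a shifted TPM scale, of the most abundant genes and of the hepatocyte share were chosen only after the result was seen, and the genes taken from the fit without ADL 3 were also chosen late. Each value named here stood apart from the other 3 lambs of its group, with a gap to the nearest of them that took most of the group's range. Such gaps arose in 34 of 406 groups of 4 values, where chance gives about 1 in 20, or 20. That rate holds for normally distributed values, while TPM were used here without log scaling. The groups also share lambs and related genes, so 20 is a rough guide and the excess was not tested. ADL 3 held 17 of them, RES 4 held 9, ADL 1, ADL 2 and RES 3 held 2 each, and RES 1 and RES 2 held 1 each. Many of the ADL 3 values are in genes picked with ADL 3 left out, so its distance in these follows in part from that choice.

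Haemoglobin genes took 0.0070% of TPM in ADL 1, against 0.000811 to 0.00182% in the other ADL lambs. The interferon list score was 0.62 in ADL 1, against -0.40 to -0.29. In ADL 2, IGFBP1 was at 8771 TPM against 2147 to 3194, and CRYAB at 37.1 against 26.1 to 27.8. The ketone body score was 0.034 in RES 3 against -0.34 to -0.29, and MTMR7 was at 0.288 TPM there against 0.556 to 0.594. SEL1L was at 28.8 TPM in RES 1 against 24.7 to 25.2, and SDF2L1 at 70.3 TPM in RES 2 against 41.9 to 44.4.

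In RES 4, SDS stood at 862 TPM against 31.1 to 68.9 in the other RES lambs, CTH at 92.0 against 34.3 to 42.2, GOT1 at 70.8 against 15.5 to 21.0 and GNMT at 34.7 against 14.9 to 17.7. ACMSD stood at 19.0 against 8.54 to 10 TPM and OAT at 8.69 against 5.42 to 5.49. CRP stood at 5607 against 1535 to 1888 TPM and UGT1A6 at 102 against 175 to 178. Its immediate early and heat shock score was -0.42, against 0.03 to 0.11.

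ADL 3 had a periportal score of -0.74 against 0.74 to 0.89 in the other ADL lambs, and a cholesterol synthesis score of -0.42 against -0.14 to -0.09. It had more transcript of ALDH1L2 (16.4 against 1.14 to 2.44 TPM), SLC12A1 (3.15 against 0.343 to 0.592), OSGIN1 (166 against 20 to 40.2), TSKU (73.4 against 6.82 to 13.8), GLYATL3 (45.5 against 2.02 to 7.21) and PYCR1 (23.8 against 1.67 to 3.79). BAAT (LOC101106409) stood at 93.6 against 26.5 to 29 TPM, SLC51B at 13.8 against 1.61 to 3.61, PKLR at 19.5 against 6.52 to 7.74, INHBC at 120 against 3.39 to 12.2 and SDF2L1 at 142 against 16.1 to 28.8. F11 stood at 54.7 against 10 to 14.8 TPM, KLKB1 at 137 against 67.4 to 76.8 and ACTA2 at 123 against 35.3 to 40.2. SLC37A4 was lower, at 45.8 against 225 to 259 TPM.

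The pattern of most weight is that ADL 3 lay away from the other ADL lambs, at 1.04 on the axis toward RES. It did not lie inside the RES group, with 46.3 on the first principal component against 14.8 to 20.6 in RES. Against a swap with a RES lamb, no RES lamb lay more than 0.375 of the way to ADL 1, ADL 2 and ADL 4. The lamb at 0.375 was RES 4, which over genes higher in RES lay at 0.448 of the way from ADL to RES. The values thus weigh less against a swap with that lamb. Against a few abundant genes as the cause, ADL 3 stayed at 0.946 of the way to RES after median-of-ratios rescaling. A RES liver under the ADL 3 label stays open. ADL 3 lay at 0.763 over the 334 genes higher in RES and at 1.23 over the 1048 lower ones. Each RES lamb was placed over as many genes picked again without it and without ADL 3. Over the higher genes RES 1, RES 2 and RES 3 lay at 0.971 to 1.08 and RES 4 at 0.448. ADL 3 thus lay below RES 1, RES 2 and RES 3 there, and within the RES range through RES 4 alone. A range that rests on 1 lamb does not decide the question. Over the lower genes the RES lambs lay at 0.743 to 1.02, so that ADL 3 lay beyond them. The label of ADL 3 gives 12.05 kg, within the ADL lambs (10.4 to 12.45 kg) and above each RES lamb (7.5 to 8.7 kg). This weight comes with the label, so it cannot show which liver was sequenced under it. A state shared with RES 4 is weighed under the other observations, and intake or health before slaughter, which may differ between single lambs of 1 group, was not tested.

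More genes fell than rose in RES without ADL 3, with 24.2% of 1382 calls higher. Against the most abundant genes as the source, 26.9% of 1644 calls were higher with the 100 most abundant genes taken out of the TPM totals. A broader shift of the TPM scale stays open and untested, because median-of-ratios rescaling, after which 52.9% of calls were higher, centres the median of all genes (from -0.13 to 0.01) and so favours balance by construction. The milk allowance, the difference that the design names, is not excluded by this test.

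T and natural killer cell markers rose in RES while cholangiocyte markers fell. A lower share of hepatocytes would raise both, and the difference of the scores moved by 0.835 (0.275 and -0.56; exact permutation p = 0.0571, n = 4 each, of a smallest possible 0.0286), which does not decide between this and a change in the cell types themselves. Neither list kept its call with an estimated correlation, and the cholangiocyte call was lost without ADL 3. Portal tracts may be sampled to a different extent in each liver piece, which these data could not test.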

How the results depend on the processing

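Settings chosen only after the data had been seen were voom on recovered reads, the acute phase covariate, list names matched by table symbol alone and the fits without ADL 3 that change a further choice; for the values below the cause was not tested. Over 148 named genes and 3085 alternatives, 2810 kept direction and side of the threshold, 259 came to pass, 10 no longer passed (all CYP26A1) and 6 reversed, in 3 genes. Apart from CYP26A1, no named gene passed in the fit of all lambs, so most of the 2810 only stayed short of the threshold. Many genes were named because they passed without ADL 3, so the 259 follow in part from that choice. These counts for genes therefore do not show that calls are robust. Over 47 lists and 1125 alternatives the numbers were 958, 25, 68 and 74, and 28 lists never reversed. Depth differed little between lambs, and genes under a mean TPM of 1 were tested only in the alternative without a filter.

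The count of genes, 1 with all 8 lambs, was 0 without a filter (1841 at an unadjusted p under 0.05), 0 with median-of-ratios rescaling (1740), 0 with voom (1765), 0 with the acute phase covariate (1615) and 1969 with sample weights. It ran from 0 to 1382 with a lamb left out, and was 49 without RES 4. Without ADL 3 it was 1171 with median-of-ratios rescaling, 1140 with quantile normalization, 1204 with voom (903 of them among the 1382) and 1463 with age as a covariate. An exact permutation test per gene put 622 at its smallest p. The authors' deposited table gives 587 genes at an adjusted p under 0.1 and 183 under 0.01.

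Whether lambs of equal number were paired cannot be settled from expression. Deviations from the group mean correlated across genes at 0.112, -0.001, -0.044 and 0.159 between lambs of equal number. The mean correlations of the same ADL lambs with RES lambs of other numbers were -0.015, 0.001, 0.007 and -0.069. With lamb number as a block, 0 genes passed (1277 at an unadjusted p under 0.05), with 17 gene lists and 2 marker lists, and the growth hormone and IGF call was lost.

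Of the 36 gene lists, 18 passed in the 8 lambs, 0 with an estimated correlation, 16 to 19 with a lamb left out and 19 with table symbols alone, not always the same lists. Of the 11 marker lists, 2 passed in the 8 lambs, 0 with an estimated correlation and with sample weights, 1 in the rank-based test and with table symbols alone, 4 with the acute phase covariate and 1 to 2 with a lamb left out.

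Medians that reversed follow. With median-of-ratios rescaling they were oxidative phosphorylation 0.028, TCA cycle 0.003, sinusoidal endothelial 0.013 and stellate 0.007. With quantile normalization they were triglyceride assembly -0.078, amino acid catabolism -0.008, sinusoidal endothelial 0.013 and stellate 0.022. With voom they were oxidative phosphorylation 0.031, TCA cycle 0.003, sinusoidal endothelial 0.01 and stellate 0.007. With age as a covariate they were triglyceride assembly -0.227, amino acid catabolism -0.087, oxidative stress -0.023, acute phase 0.105, one carbon -0.034 and B cell -0.065. With sample weights they were triglyceride assembly -0.011, amino acid catabolism -0.068, insulin -0.001, autophagy -0.044, Kupffer cell -0.03, stellate 0.007 and B cell -0.109. With the acute phase covariate they were triglyceride assembly -0.253, amino acid catabolism -0.082, acute phase 0.106, one carbon -0.056, B cell -0.065 and the gene FGF21 -0.018. With a pseudocount of 1 the B cell median was -0.022. With table symbols alone they were triglyceride assembly -0.048, oxidative phosphorylation 0.046 and iron 0.01, and oxidative stress passed (0.16, adjusted p = 0.0177).

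With a lamb left out, the lowest and highest medians of lists that reversed were fatty acid oxidation -0.321 and 0.045, triglyceride assembly -0.265 and 0.181, amino acid catabolism -0.145 and 0.152, insulin -0.128 and 0.25, oxidative stress -0.053 and 0.24, acute phase -0.706 and 0.072, interferon -0.132 and 0.539, oxidative phosphorylation -0.139 and 0.102, TCA cycle -0.17 and 0.074, autophagy -0.039 and 0.111, iron -0.121 and 0.021 and one carbon -0.097 and 0.219. Among markers they were hepatocyte -0.044 and 0.398, sinusoidal endothelial -0.095 and 0.041, stellate -0.173 and 0.137, erythroid -0.017 and 0.187, B cell -0.342 and 0.128 and mitochondrially encoded -0.328 and 0.187. Genes that reversed ran from -0.142 to 0.534 (IGFBP1) and -0.686 to 0.20 (TRIB3). The RES minus ADL difference in the share of the 10 most abundant genes ran from -2.53 to 1.54 percentage points and in the mitochondrial share from -1.77 to 0.56.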

Other observations

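The test of an acute phase state shared with RES 4 and the counts of other splits for single genes in the 8 lambs and with the best lamb left out were chosen only after the result was seen; the retinoid test was chosen after CYP26A1 and before its other genes had been seen, and the other counts of splits were chosen before theirs. Further genes of amino acid breakdown changed in RES without ADL 3, in both directions. Genes that fell were BCAT2 (log2 fold change -2.65, SE 0.54), histidine ammonia-lyase (HAL, -2.22, SE 0.37), AASS (-1.72, SE 0.26), tryptophan dioxygenase (TDO2, -1.13, SE 0.29) and the ornithine carrier SLC25A15 (-1.34, SE 0.24). Genes that rose were glutamate dehydrogenase (GLUD1, 1.28, SE 0.17), KYNU (1.16, SE 0.28), SARDH (1.09, SE 0.14), IVD (0.91, SE 0.17) and AGXT2 (0.82, SE 0.15). Each passed at an adjusted p under 0.05 without ADL 3 and none passed in the 8 lambs; they lie outside the rule for named genes and were picked after their values had been seen, as were those of the next paragraph.

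In the same fit, the carbohydrate response factor MLXIPL (1.27, SE 0.23), the acetate enzyme ACSS2 (1.09, SE 0.20), the phosphofructokinase PFKL (1.01, SE 0.18) and FDFT1 of cholesterol synthesis (1.40, SE 0.33) rose. ATP citrate lyase (ACLY, -0.87, SE 0.18) and the aldolase ALDOA (-1.09, SE 0.18) fell. Of the TCA cycle, IDH3A (-0.80, SE 0.20), SUCLA2 (-0.76, SE 0.17) and DLST (-0.61, SE 0.15) fell. Whether these calls hold after rescaling was not examined for single genes here.

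As a hypothesis, the rise of CYP26A1, a gene known to be induced by retinoic acid, may be part of a wider rise of retinoic acid target genes. Of 13 further targets listed beforehand and not looked at before, 8 were tested, 7 were higher in RES and the median log2 fold change was 0.25 (p = 0.12 in camera with an estimated correlation, p = 0.0447 at the preset correlation, each a model fitted across all genes). Of these 7, NRIP1 (0.002) and RDH10 (0.028) lay near 0 and were below 0 without ADL 3 (-0.179 and -0.106), which leaves 5 of 8 higher there. RARB had a log2 fold change of 0.44 (SE 0.17), and TGM2 (0.83) and DHRS3 (1.11), whose values had been seen earlier and which were therefore left out of the test, passed without ADL 3 (adjusted p = 0.0131 and 0.0273). The bound set in advance, a p at or above 0.05, was met, but it was the wrong bound, since a p over the threshold from 8 genes does not exclude a rise. That reading was settled after the p was seen, and the hypothesis stays undecided.

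A further hypothesis was that ADL 3 and RES 4, the lambs with the highest acute phase scores, share a state that could place ADL 3 near RES. Outside the acute phase, complement and coagulation lists, the deviation of ADL 3 from the other ADL lambs and that of RES 4 from the other RES lambs correlated at 0.093 across 13748 genes, but ADL 3 deviates toward RES and RES 4 toward ADL, so that their opposite shifts on the axis between the groups mask what they share. With that axis removed the correlation was 0.512, against 0.051, -0.024 and 0.061 for RES 1, RES 2 and RES 3, and the second principal component also placed ADL 3 (-36.5) and RES 4 (-22.8) apart from the other RES lambs (24.1 to 28.9). The hypothesis stays undecided, since a shared state that moves ADL 3 toward RES would not by itself move RES 4 toward ADL (0.375 of the way). Genes are not independent replicates, and the step of removing the axis was chosen after the first correlation had been seen.

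Among the 334 genes that rose without ADL 3, ADL 3 lay nearer to ADL 1, ADL 2 and ADL 4 than to RES in 99, and among the 1048 that fell it did so in 31. For each RES lamb as many genes were picked again from a fit without it and without ADL 3, and it lay nearer to these ADL lambs in 23 (RES 1), 49 (RES 2), 24 (RES 3) and 173 (RES 4) of 334 and in 57 to 153 of 1048.

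The 8 lambs can be split into groups of 4 in 35 ways, and the 7 lambs without ADL 3 into groups of 4 and 3 in 35 ways. For genes in the 8 lambs, 4 of 35 splits gave as many as the 1 of the real split (highest other 2), so chance cannot be excluded. For gene lists, the real split gave 18 and the highest other 17, so 1 of 35 was as large, the smallest share that 35 splits allow. The bound set in advance, a share of splits under 0.05, was thus met. The margin is 1 list, however, and 0 lists passed with an estimated correlation. Chance is therefore not taken as excluded for the gene lists, a reading more cautious than the bound and settled after the counts were seen. For marker lists, 28 of 35 gave at least the 2 of the real split (highest other 6), and chance cannot be excluded. Without ADL 3, the real split gave 1382 genes and the highest other 143, the split that places RES 4 with ADL 1, ADL 2 and ADL 4. Thus 1 of 35 was as large, which met the same bound, but ADL 3 had been left out because of its effect. With the lamb that gives the most genes left out of each split of the 8, the real split gave 1382 and the highest other 829, so 1 of 35 was as large. The next 4 splits (521 to 829 genes) each left out a RES lamb. Each set ADL 1, ADL 2 and ADL 4 against ADL 3 and the other RES lambs. This points to a structure of the samples in which ADL 3 lies on the side of RES. The count with the best lamb left out of each split met the same bound. As 5 of 35 splits carry this structure, and the test was chosen after the 1382 had been seen, chance cannot be excluded for this gene count. For gene lists without ADL 3, 3 of 35 gave at least 17 (highest other 18), and for marker lists 22 of 35 gave at least 2 (highest other 6), so chance cannot be excluded for either. The counts of lists without ADL 3 do not take the choice of that lamb into account.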
